A study of Homo sapiens with 4 samples.

How the data were processed

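RNA from dish cultures of SAS-Fucci cells was extracted with a column kit, labelled by low-input linear amplification with Cy3 and hybridized to 4 one-colour Agilent SurePrint arrays of 1 design, all on 1 slide. The groups Control, KRTAP2-3 expressed, Wild type and KRTAP2-3 knockout were taken from the genotype labels of the samples, with 1 array in each. The pairing of expressed with Control and of knockout with Wild type was inferred from the labels and from the authors' table, whose columns pair the same arrays.

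Per the file headers, each array was scanned and read with Agilent Feature Extraction 12.0.3.1, which gave a processed intensity per spot after background subtraction and detrending within the array, with no normalization between arrays, and an error of that intensity. The same deposited files hold the mean intensity of the spot and the median intensity of its local background. The authors also deposited a table of log2 ratios of 34248 probes, expressed against Control and knockout against Wild type, filtered on detection on all 4 arrays. Of its columns 2 were used and 10 were not, since those repeat the raw values, hold 0 or annotate the probe. For 34200 matched probes the authors' log2 ratio equalled the log2 ratio of the processed intensities minus 0.0161 (expressed) or 0.0620 (knockout), within 0.001 for 100% of 33910 probes with a single spot.

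For the values reported here, control spots and spots called outliers by the scanner software (63 to 84 per array) were left out, the processed intensity was taken to log2, each array's 75th percentile over its 58201 probes that are not controls was subtracted, and spots of the same probe were averaged. Probe names came from the array files, updated through RefSeq accessions for 31104 probes. Left out were 1135 probes that match transcripts of several genes, 1507 without a gene name, and 125 Y-linked or XIST probes. The shared probe of KRTAP2-1, KRTAP2-2, KRTAP2-3 and KRTAP2-4 was kept for the level of KRTAP2-3 alone. The remaining 55434 probes gave 41405 gene names, 20142 of them gene symbols, each represented by its brightest probe over the 4 arrays, and 31862 were well above background on at least 1 array. Probe positions are those of hg19 in the array files.

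Differences were computed as expressed minus Control and knockout minus Wild type, with Wild type minus Control as a yardstick. A gene counted as at least 2-fold different when its log2 difference was at least 1 in size and the array with the higher signal was well above background by the software's call. With 1 array per group no test was made and no p-value is given. The error of a difference combines the software's errors of the spots. For a gene at background on the lower array, the fold is a bound against the lowest signal well above background on that array (8.14 to 9.43).

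Gene lists, 37 in all, were written before the data were examined, as were the comparisons, the rule for named genes and all alternatives except those with a signal of at least 100. A list is summarized by the median log2 difference of its members that are well above background on at least 1 array of the comparison. It is called apart when that median lies below percentile 2.5 or above percentile 97.5 of 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles describe these arrays and are not p-values. Overlaps between comparisons were set against the product of both shares (independence), and for comparisons that share an array also against 20 simulations without an effect.

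Genes were named by a rule. KRTAP2-3, TGFB1, TGFB2, TGFB3, TGFBR1 and TGFBR2 are always named. In each main comparison the 10 largest higher and 10 largest lower genes among those with a gene symbol, well above background and unsaturated on both arrays, and with their other probes in the same direction, may be named, and likewise the 10 genes per direction with the largest smaller difference among those opposite in both comparisons. For genes at background on 1 array the 5 largest bounds per direction qualify, and from each gene list up to 4 members of at least 2-fold, or else 2. Names outside this rule are said to be chosen after their values were seen.

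The calls were tested on simulated data. The Wild type values plus noise of SD 0.15 took the place of the knockout array, with 27672 genes. All 100 genes shifted by 1.5 and all 50 shifted by 3 were called, 1 of 50 shifted by 0.5, and 0 of 27472 unchanged genes. All 5 lists shifted by 0.3 stood apart, as did 2 of 37 unshifted lists. The noise was equal for all genes and far below the threshold of 1, so the 0 of unchanged genes was all but fixed in advance. The real knockout minus Wild type differences had an SD of 0.418 at signals of at least 100 and 0.692 below. The simulation thus gives no rate of false calls for these arrays.

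Alternatives were normexp background correction with an offset of 50, quantile normalization and scaling to the median of probes measured on all 4 arrays. Others were detection on all 4 arrays, no filter on dim probes, the mean over a gene's probes and the authors' table. Thresholds of 1.5-fold and 3-fold and a requirement that the difference exceed 1.96 times its error were tried too. For lists the mean and unmatched random lists were added. The Control and Wild type arrays were also exchanged as comparators. Their labels name no manipulation of KRTAP2-3 but do not say whether Control carries a vector. A minimum signal of 100 was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for normexp.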

Results

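Gene expression was measured in SAS-Fucci cells, a derivative of SAS, an established human tongue squamous carcinoma line, that carries a fluorescent reporter of the cell cycle. The cells grew in dishes, and RNA from each culture was hybridized to a one-colour Agilent expression array. The series holds 4 arrays in 4 groups, namely Control, KRTAP2-3 expressed, Wild type and KRTAP2-3 knockout, with 1 array per group. KRTAP2-3 encodes a keratin-associated protein, a member of a family known from the keratin network of hair. The title of the series links the gene to the response of cancer cells to TGF-β, to proliferation and to migration. With 1 array per group there were no replicates and no tests, so every difference below describes these arrays, and their number limits the precision. Each error is the scanner software's error of the spots and leaves out the variation between cultures. At bright probes it rose in proportion to the signal, with 476 at a signal of 4760 and 1481 at 14810. Differences between bright signals therefore carry nearly the same error, 0.20, which is not a spread measured for the gene. All 4 arrays came from 1 slide, so array position and group cannot be told apart.

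Each array held 60901 spots for transcripts, which came from 58201 probes. The share of spots well above background was 71.1% on the Control array, 65.1% on the expressed array, 66.0% on the Wild type array and 69.3% on the knockout array. No spot was saturated. The 75th percentile of the signals lay between 222 and 232, and the median signal lay between 22.9 on the expressed array and 31.7 on the Control array. Spots of the same probe differed by an SD of 0.0716 to 0.0843 on the log2 scale, over 291 to 292 probes with at least 5 spots.

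The knockout array carried far less signal at the probe for KRTAP2-3 than the Wild type array did. This probe, on chromosome 17 at positions 39215578 to 39215637 of hg19, gave signals of 979 ± 97.9 on the Control array, 786 ± 78.7 on the expressed array, 1648 ± 165 on the Wild type array and 292 ± 29.2 on the knockout array (software error). Knockout minus Wild type was −2.56 ± 0.20 on the log2 scale, a 5.90-fold lower signal. The array labelled KRTAP2-3 expressed was not higher at this probe, with −0.33 ± 0.20 against Control. A second probe, at positions 39221320 to 39221369 of the same chromosome, matches transcripts of KRTAP2-1, KRTAP2-2, KRTAP2-3 and KRTAP2-4. Its signals were 4760, 14810, 4350 and 4566 in the same order, 1.62 higher on the expressed array than on Control (3.08-fold) and with a difference of 0.01 between knockout and Wild type. Among probes that match KRTAP2-3, the array labelled KRTAP2-3 expressed therefore had the higher signal only at the shared one. Among them the knockout had the lower signal only at the gene's own probe. Dim probes for KRTAP2-1 alone and KRTAP2-2 alone were not higher on the expressed array, with −0.44 and −2.09 against Control, the latter at background. The probe for KRTAP2-4 alone was at background on every array. Knockout minus Wild type was 0.20 for KRTAP2-1 and −0.93 ± 0.36 for KRTAP2-2. Whether either probe that matches KRTAP2-3 lies inside the expressed construct or the deleted part was not checked, and directions below follow the labels.

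**Figure D1:**
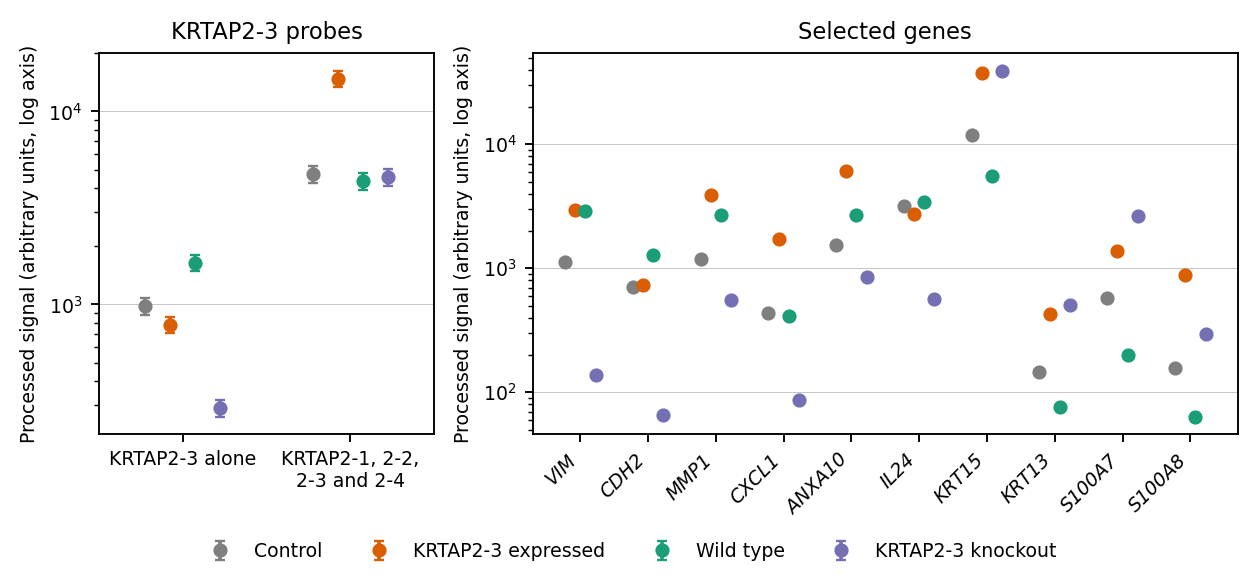
Processed signal on a log axis for the KRTAP2-3 probes (left, with bars for the scanner software's error) and for 10 genes (right, without bars) on the 4 arrays, with 1 point per array. The gene's own KRTAP2-3 probe is lowest on the knockout array (292), while the probe shared with KRTAP2-1, KRTAP2-2 and KRTAP2-4 is highest on the expressed array (14810).

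Neither the Wild type nor the Control array carries a manipulation by its label, so their difference served as the yardstick for both comparisons. The authors' table names the comparator of the expressed array CSIIEF, and the labels do not say whether the Control cells carry a vector or are the same cells as Wild type. Between them 3817 of 30753 measured genes differed at least 2-fold, 299 higher and 3518 lower on the Wild type array. Of the lower genes, 95.7% had signals under 100 on both arrays. Among 14461 genes with a signal of at least 100 on either array, 241 differed at least 2-fold, 90 higher and 151 lower on the Wild type array. Genes of AP-1 and the immediate early response had a median of 0.37 and ribosome biogenesis and MYC target genes of 0.59, while keratinocyte differentiation genes had a median of −0.57, keratins −0.28 and antigen presentation genes −0.32. Fibroblast markers had the lowest median of the lists that stood apart (−0.66, percentile 0.74), with 10 of 11 below 0. In all, 16 of the 37 gene lists stood apart from random lists of equal size and expression, 8 higher and 8 lower. By chance 1.85 would do so. Differences of this size separated arrays whose labels name no manipulation of KRTAP2-3, although the gene's own probe was 0.76 ± 0.20 higher on the Wild type array.

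The knockout and Wild type arrays address how cells labelled as lacking KRTAP2-3 differ, though the knockout array kept a signal above background at the gene's own probe. Genes of the mesenchymal state were among the most strongly lower on the knockout array. VIM, which encodes the intermediate filament protein vimentin, had a signal of 2884 on the Wild type array and 139 on the knockout array, 21.7-fold lower (−4.44 ± 0.21). CDH2, which encodes N-cadherin, had signals of 1275 and 66.0, 20.2-fold lower (−4.33 ± 0.21). The Control array lay between, with 1120 for VIM and 709 for CDH2. On the other side, S100A7, an antimicrobial protein of differentiating epithelium, was 3.67 ± 0.20 higher (200 to 2654), and ZNF750, a transcription factor of epidermal differentiation, was 3.30 ± 0.23 higher (26.1 to 268). Across all genes, 2477 of 30150 differed at least 2-fold, 1541 higher and 936 lower on the knockout array. Among 14398 genes with a signal of at least 100 there were 487, and lower genes then outnumbered higher ones, 303 against 184.

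Of 25 measured mesenchymal genes, 6 were at least 2-fold lower, 1 was higher and 18 were neither, and the list median of −0.30 lay at percentile 0 of matched random lists. Beside VIM and CDH2, FN1, which encodes fibronectin, was lower by −1.56 ± 0.27, and ZEB1, a repressor of epithelial genes, was at least 5.12-fold lower, being at background on the knockout array. Matrix proteases and their inhibitors had a median of −0.59 (percentile 0), with 11 of 23 lower and 0 higher. MMP1, an interstitial collagenase, differed by −2.33 ± 0.20, SERPINE2 by −1.59 ± 0.22 and PLAUR, the urokinase receptor, by −1.37 ± 0.21. NF-κB targets, cytokines and chemokines had a median of −0.59 (percentile 0) and members on both sides, 11 lower and 5 higher of 31. IL24 (−2.66 ± 0.20) and the chemokine gene CXCL1 (−2.32 ± 0.21) were lower, while LCN2, which encodes the iron-scavenging protein lipocalin 2, was higher (3.00 ± 0.21). AP-1 and immediate early genes had a median of −0.65 (percentile 0), with 8 of 28 lower and 1 higher, among them DUSP4 (−1.91 ± 0.20), KLF6 (−1.50 ± 0.20) and the higher EGR3 (1.92 ± 0.21). Against the Control array the medians of these 4 lists were −0.48, −0.80, −0.69 and −0.11, all still apart and below 0, the last far nearer to it. Fibroblast markers had a median of −0.12 (percentile 7.88), not apart, with 7 of 11 below 0. They lay below 0 under all 12 settings and were apart under 2, the Control array as comparator among them.

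Several lists of adhesion, stress and metabolism were lower as well. Integrins and laminins had a median of −0.17 (percentile 0.15), with 1 of 26 lower, ITGB5 (−1.23 ± 0.20). Actin cytoskeleton and YAP/TEAD target genes had a median of −0.16 (percentile 0.21), with 4 of 27 lower, including ANKRD1 (−2.33 ± 0.22), NT5E (−1.89 ± 0.20) and CCN2, a matricellular growth factor (−1.41 ± 0.21). Metallothioneins had a median of −0.38 (percentile 0.02), with MT1F at −1.01 ± 0.20. Glycolysis genes (−0.15, percentile 0.53), unfolded protein response and ATF4 target genes (−0.17, percentile 0.19) and ribosome biogenesis and MYC target genes (−0.13, percentile 0.84) were also apart, but against the Control array their medians were 0.07, 0.22 and 0.44. As means the integrin, glycolysis and ribosome biogenesis lists were not apart, nor were glycolysis genes under quantile normalization.

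Keratinocyte differentiation genes were higher on the knockout array, with a median of 0.27 (percentile 99.4), 6 of 25 at least 2-fold higher, 0 lower and 9 below 0, and were not apart without the filter on dim probes. S100A8 (2.16 ± 0.21) and S100A9 (2.07 ± 0.20), the subunits of calprotectin, joined S100A7 and ZNF750. Antigen presentation genes had a median of 0.41 (percentile 100), with 15 of 16 above 0 and 2 at least 2-fold higher, CIITA (1.43 ± 0.23) and HLA-B (1.07 ± 0.20). Against the Control array both medians were −0.04 and neither list was apart, although S100A7 (2654 against 572), ZNF750 (268 against 80.1) and CIITA (71.8 against 25.5) also had higher signals on the knockout array than on Control, while HLA-B did not. S100 and annexin genes had a median of 0.16 (percentile 99.9) but a mean of −0.05, with ANXA10 at −1.71 ± 0.20, and their median was −0.09 against Control. Epithelial junction genes had a median of 0.09 (percentile 98.8), with DSC3, a desmosomal cadherin, higher (1.29 ± 0.20) and CLDN4, a tight junction protein, lower (−1.68 ± 0.20), and it was not apart against Control (0.03), as a mean or beside unmatched random lists. Keratins differed in both directions, with 4 higher and 4 lower of 19. KRT15 (2.77 ± 0.20), KRT13 (2.68 ± 0.21) and KRT14 (1.82 ± 0.20) were higher and the hair keratin gene KRT86 (−1.90 ± 0.20) was lower. The keratin median was −0.27 (percentile 0.01), the mean 0.0035, and the list was not apart as a mean or without the filter on dim probes.

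The TGF-β lists were not apart by their medians. TGF-β and SMAD target genes had a median of 0.03 (percentile 65.7) and a mean of −0.12, with 3 at least 2-fold lower, CCN2 and INHBA (−1.20 ± 0.20) among them, 0 higher and 25 neither, and against the Control array the median was −0.14 and apart. TGF-β family ligands and receptors had a median of 0.01 (percentile 39.6) and a mean of −0.22 that was apart, with 4 of 27 lower, namely INHBB (signals of 297 and 77.5), INHBA, TGFB2 (−1.06 ± 0.20) and the BMP antagonist NOG, which was at least 6.73-fold lower. TGFB1 differed by −0.14, TGFB3 by 0.66, TGFBR1 by 0.11 and TGFBR2 by −0.66, each below 2-fold. Cell cycle genes did not stand apart, with medians of 0.05 for G1/S and DNA replication (percentile 95.6) and 0.03 for G2/M and mitosis (percentile 90.8), and 0 of 30 members at least 2-fold different in either list. The G1/S list was apart as a mean (0.11) and against the Control array, where its median was 0.40. Interferon-stimulated genes had a median of 0.15 at percentile 97.4, not apart, but were apart under 7 of 12 settings, and had a median of −0.09 against the Control array. The medians of all 22 lists that did not stand apart lay between −0.24 and 0.16.

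The remaining genes with the largest differences on the knockout array included TNFSF10, which encodes the death ligand TRAIL (3.21 ± 0.20), the protease inhibitor gene SERPINB4 (3.19 ± 0.21), EDIL3 (3.13 ± 0.23) and BACE2 (2.93 ± 0.20). On the lower side were the cancer-testis antigen gene MAGEB2 (−3.83 ± 0.21), TMEM200A (−3.43), HSD11B1, which encodes an enzyme that activates glucocorticoids (−3.28), and IL1RL1, the interleukin 33 receptor gene (−3.06). Among genes at background on the other array, PSAPL1 was at least 30.4-fold higher and ECSCR at least 13.1-fold lower on the knockout array.

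With the Control array as comparator, 182 of the 303 genes lower on the knockout array at a signal of at least 100 were also at least 2-fold lower (60.1%). Simulated arrays without an effect gave 28.3%, since both differences share the knockout array, and 6.03 genes would overlap by independence. For the 184 higher genes the share was 35.9%, against 30.2% in the simulation. The simulation is a rough baseline, since for the lower genes of the expressed array it gave 27.8% where 5.36% was seen. A share above it can come from the knockout or from any other trait of that 1 array or culture, and does not tell them apart.

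**Figure D2:**
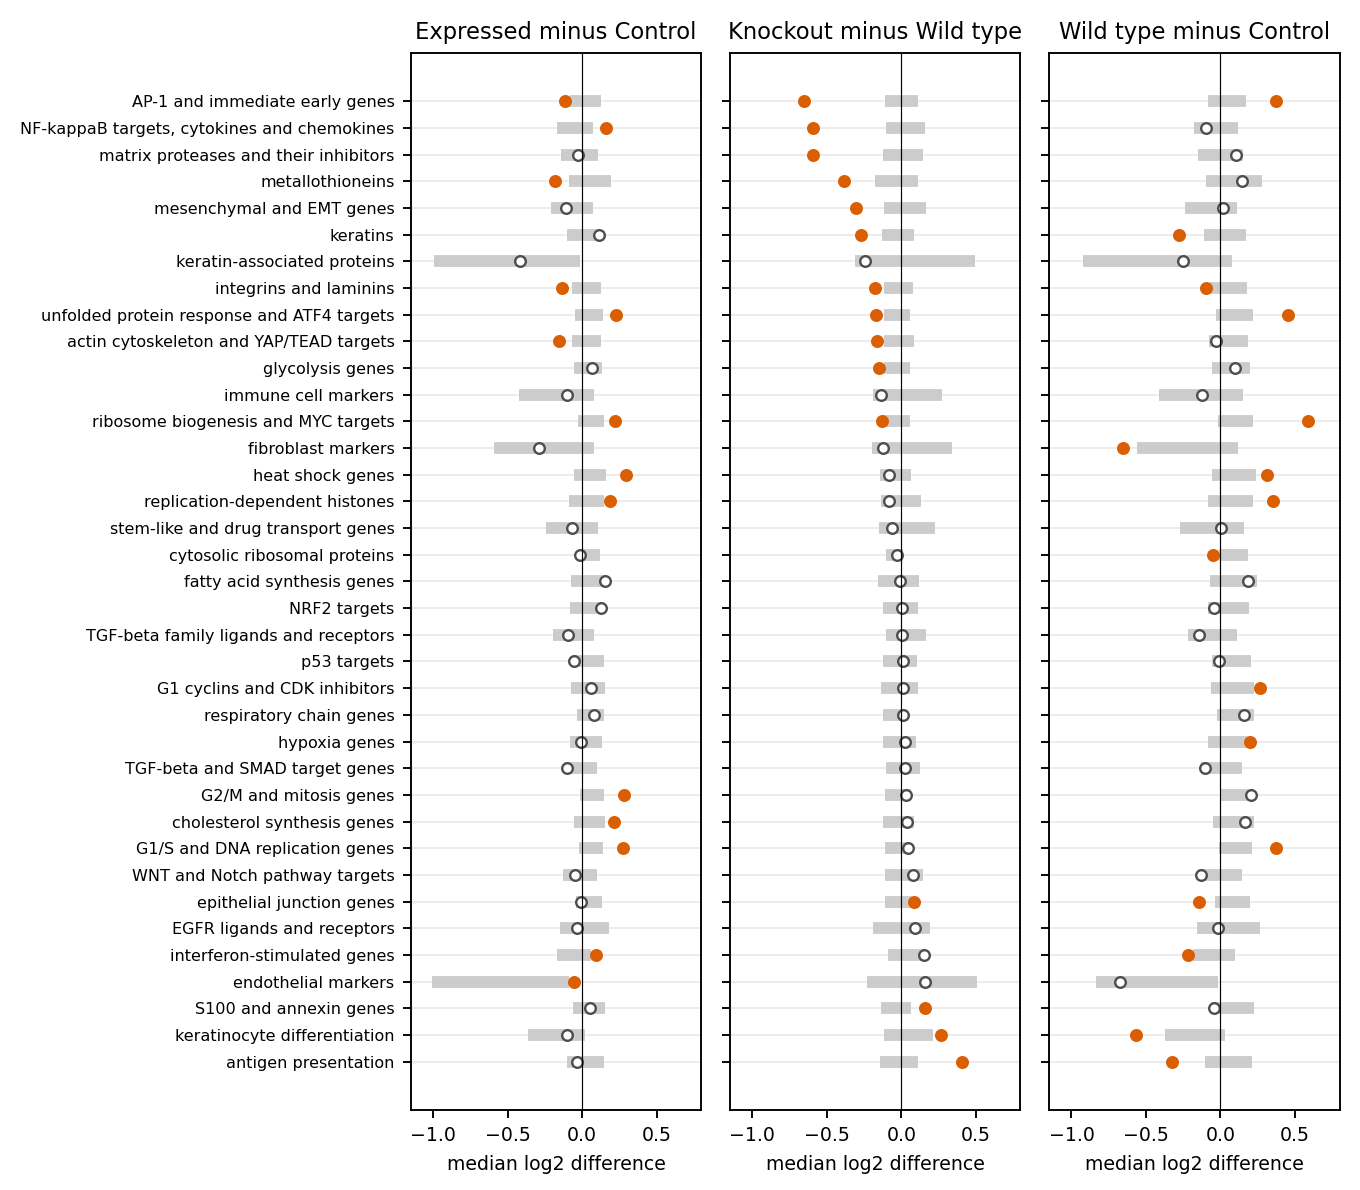
Median log2 difference of each of the 37 gene lists for knockout minus Wild type, expressed minus Control and Wild type minus Control, with grey bars for the central range of random lists of equal size and expression and filled points for medians outside it. The mesenchymal, protease, cytokine and AP-1 lists lie below 0 for knockout minus Wild type (−0.30, −0.59, −0.59 and −0.65), and the TGF-β target list lies at 0.03.

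The expressed and Control arrays address the effect of expressing KRTAP2-3, by the labels and not by the gene's own probe. Among genes measured on both arrays, the largest higher values included KRTAP20-2 (2.55 ± 0.20, from a signal of 209 to 1239), the calprotectin subunit gene S100A8 (2.49 ± 0.21, 156 to 884), the matrix protein gene EDIL3 (2.20 ± 0.21), LYPD1 (2.09, 1200 to 5152), KRT6A, a keratin of activated keratinocytes (2.06 ± 0.21, 122 to 512), the neutrophil chemokine gene CXCL1 (1.98 ± 0.20, 433 to 1728), ANXA10 (1.97 ± 0.20) and KRTAP9-1 (1.89, 1002 to 3761). KRTAP20-2 and KRTAP9-1 encode other keratin-associated proteins, and whether their probes also bind KRTAP2-3 transcripts was not tested. At least 2-fold differences were found for 4418 of 30712 genes, 229 higher and 4189 lower on the expressed array, and 98.7% of the lower genes had signals under 100 on both arrays. With a signal of at least 100 on either array the count was 98 of 14456, 42 higher and 56 lower. That is fewer than the 241 that separated the Wild type and Control arrays. Of the 42 higher genes 28 (66.7%) were also at least 2-fold higher than on the Wild type array, where simulated arrays without an effect gave 31.6%, and of the 56 lower genes 3 (5.36%), where they gave 27.8%. As both differences share the expressed array, a share above the simulated one can also come from other traits of that array or culture.

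NF-κB targets, cytokines and chemokines had a median of 0.16 (percentile 100), with 4 of 30 at least 2-fold higher, 0 lower and 12 below 0. CXCL1 was joined by CXCL2 (1.09 ± 0.20) and by CXCL3, at least 3.39-fold higher and at background on the Control array. The percentile fell inside the random range when a gene's probes were averaged. Keratins had a median of 0.11 (percentile 97.0), not apart, but were apart under 9 of 12 settings, with 0.16 at signals of at least 100 and 0.70 against the Wild type array. They had KRT6A, KRT15 (1.65 ± 0.20) and KRT13 (1.54 ± 0.21) among 4 higher and KRT23 (−1.62 ± 0.20) as the 1 lower of 20. Keratinocyte differentiation genes had a median of −0.10 (percentile 69.6), a mean of 0.18, and with signals of at least 100 a median of 0.48 that was apart, with S100A8, S100A7 (1.25 ± 0.20) and S100A12 (1.47 ± 0.27) higher. Matrix proteases had a median of −0.03 (percentile 38.2) and a mean of 0.10 that was apart, with the collagenase genes MMP1 (1.68 ± 0.20) and MMP13 (1.66 ± 0.24) higher and 21 neither. Mesenchymal genes were not apart (−0.11), although VIM was higher (1.39 ± 0.20), as was CDH11, at least 3.25-fold, while PDGFRB (−1.12 ± 0.23) was lower.

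Cell cycle genes were slightly higher together. All 30 G1/S and DNA replication genes and all 30 G2/M and mitosis genes lay above 0, with medians of 0.28 in both lists (percentile 100), and 0 of them reached 2-fold. The largest were RRM2, a subunit of ribonucleotide reductase (0.94 ± 0.20), and CCNE2, which encodes cyclin E2 (0.75 ± 0.20). The Wild type array was also above Control for these lists, with 0.37 and 0.20, the latter not apart (percentile 94.8). Against the Wild type array the G1/S median of the expressed array was −0.10. The G2/M list stayed above 0 and apart under all 12 settings, that comparator included, with a lowest value of 0.10. Other growth and stress lists were like the G1/S list. Heat shock genes had a median of 0.29, unfolded protein response and ATF4 target genes 0.23, ribosome biogenesis genes 0.22 and replication-dependent histones 0.18. The percentiles of these lists ran from 99.6 to 100. Their Wild type minus Control medians were 0.31, 0.45, 0.59 and 0.35, and against the Wild type array the expressed array gave −0.02, −0.25, −0.30 and −0.21. Cholesterol synthesis genes had a median of 0.22 (percentile 99.9), with SC5D (−0.50) and IDI1 (0.49) the largest, but Wild type minus Control was 0.17 and against the Wild type array the list was not apart (0.038). Interferon-stimulated genes had a median of 0.09 (percentile 99.6), against −0.22 for Wild type minus Control.

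Integrins and laminins (−0.14, percentile 0.10), actin cytoskeleton and YAP/TEAD target genes (−0.16, percentile 0.01), AP-1 and immediate early genes (−0.11, percentile 0.61) and metallothioneins (−0.18, percentile 0.10) were lower. None of these 4 was apart from random lists that were not matched on expression, and against the Wild type array the integrin (−0.05) and actin medians (−0.07) were not apart. Few members reached 2-fold, MYL9, a myosin light chain gene (−1.81 ± 0.28, from a dim signal), among them. TGF-β and SMAD targets had a median of −0.10 (percentile 4.52), not apart, and at percentile 0.87 with signals of at least 100, with NEDD9 (−1.13 ± 0.25) the 1 of 28 at least 2-fold lower and 0 higher. TGF-β ligands and receptors also had a median of −0.10 (percentile 26.3, or 2.40 with signals of at least 100), and TGFB1 (−0.17), TGFB2 (−0.66), TGFB3 (0.41), TGFBR1 (−0.08) and TGFBR2 (−0.24) all stayed below 2-fold. Markers of endothelial cells, of which 1 reached a signal of 100, stood above their random lists with a median of −0.05 (percentile 98.4) that was 0.15 under quantile normalization and 0.26 against the Wild type array, and they were apart under only 3 of 11 settings. Fibroblast (−0.29) and immune cell markers (−0.10) did not stand apart. The list of keratin-associated protein genes, which holds neither KRTAP20-2 nor KRTAP9-1, had a median of −0.42 (percentile 59.0), with 0 of 10 higher and 3 lower. The medians of all 23 lists that did not stand apart lay between −0.42 and 0.15.

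The lower genes of this comparison were dim. The 10 with the largest lower values, among them MIR143HG (−1.96), the dynein gene DNAH9 (−1.96), the endothelial adhesion gene SELE (−1.94) and the growth factor genes FGF8 (−1.89) and FGF10 (−1.88), had Control signals between 31.8 and 65.0 and errors between 0.27 and 0.38. Spike-in RNAs, added in equal amount to every sample, had the same tilt. The 3 dim ones had a median of −0.83 for expressed minus Control (−1.16 to −0.55), the 7 bright ones −0.15 (−0.19 to −0.07). Quantile normalization moved the median of all genes by 0.117 in this comparison and by 0.110 for Wild type minus Control, and it left 841 genes higher and 1457 lower.

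**Figure D3:**
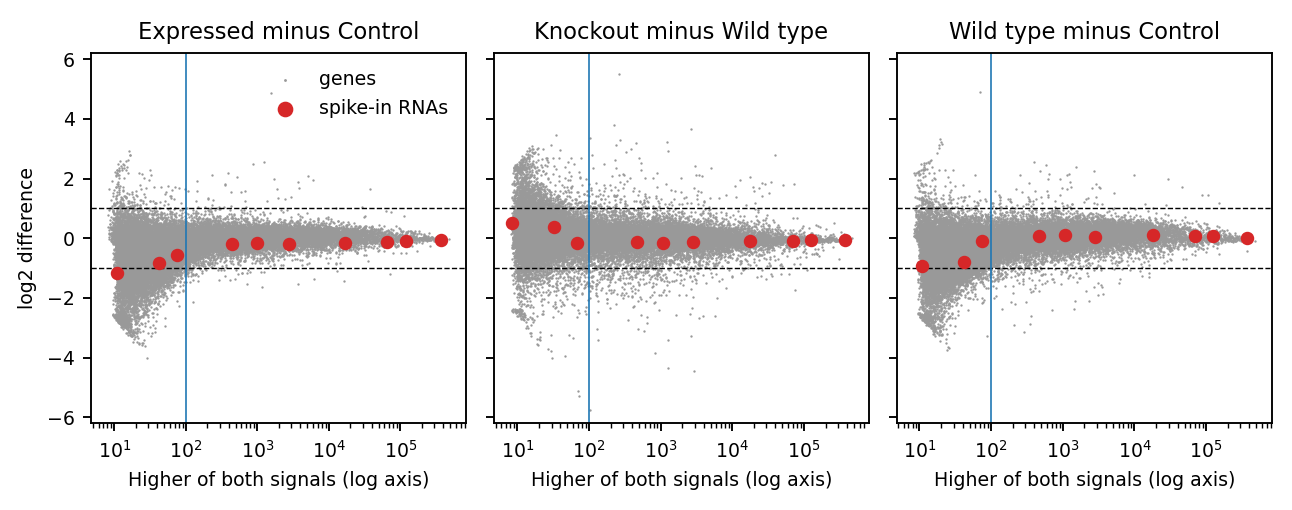
Log2 difference of each gene against the higher of its 2 signals on a log axis for 3 pairs of arrays, with spike-in RNAs in red, dashed lines at 2-fold and a vertical line at a signal of 100. Below a signal of 100 the genes of expressed minus Control and Wild type minus Control lie mostly below 0, with medians of −0.52 and −0.46, and those of knockout minus Wild type lie above, with 0.15.

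Genes that differed in opposite directions in the 2 comparisons, which share no array, bear on the question of a graded response to KRTAP2-3. Among 29000 genes measured in both, 31 were at least 2-fold higher on the expressed array and at least 2-fold lower on the knockout array, where 4.31 would be by independence. Another 31 were at least 2-fold higher in both, where 6.43 would be. The opposite genes included VIM (1.39 and −4.44), CXCL1 (1.98 and −2.32), NTF3, a neurotrophin gene (1.79 and −2.11), ANXA10 (1.97 and −1.71), MMP1 (1.68 and −2.33), MMP13 (1.66 and −1.27), KRT6A (2.06 and −1.28) and DPYSL2 (1.23 and −1.67). MMP1 had signals of 1198 on Control, 3882 on the expressed array, 2700 on Wild type and 559 on the knockout array. In the other direction were 408 genes, where 134 would be by independence. Of these, 7 remained when a signal of at least 100 was required. Most genes at least 2-fold lower on the expressed array (98.7%) or higher on the knockout array (88.1%) had signals under 100. There the differences tilt in opposite directions, with medians of −0.52 and 0.15. The count by independence was taken over all signals, so the excess over 134 does not separate a graded response from this tilt. The 31 and 408 genes became 82 and 112 under quantile normalization, 6 and 3 under normexp, and 15 and 59 with detection on all 4 arrays. The brighter ones of the 408 included the folate receptor genes FOLR1 (−1.55 and 1.17) and FOLR3 (−1.55 and 1.22) and FAM181B (−1.13 and 1.14). FOLR1 gave signals of 3659, 1267, 988 and 2321, so the expressed and Wild type arrays lay close to each other.

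Genes that differed the same way were nearly as common among the brighter genes. With signals of at least 100, 18 of 14097 genes differed in opposite directions (1.11 by independence) and 13 in the same direction (1.04 by independence). Of those higher on the expressed array, 11 were lower and 12 higher on the knockout array. EDIL3 (2.20 and 3.13), KRT15 (1.65 and 2.77), KRT13 (1.54 and 2.68), S100A8 (2.49 and 2.16) and S100A7 (1.25 and 3.67) were higher in both. Across these genes the 2 differences were correlated with Pearson's r of 0.10 and Spearman's rho of 0.10, and across all 29000 genes with −0.18 and −0.15. Genes are not independent replicates, and no test was made of either value.

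**Figure D4:**
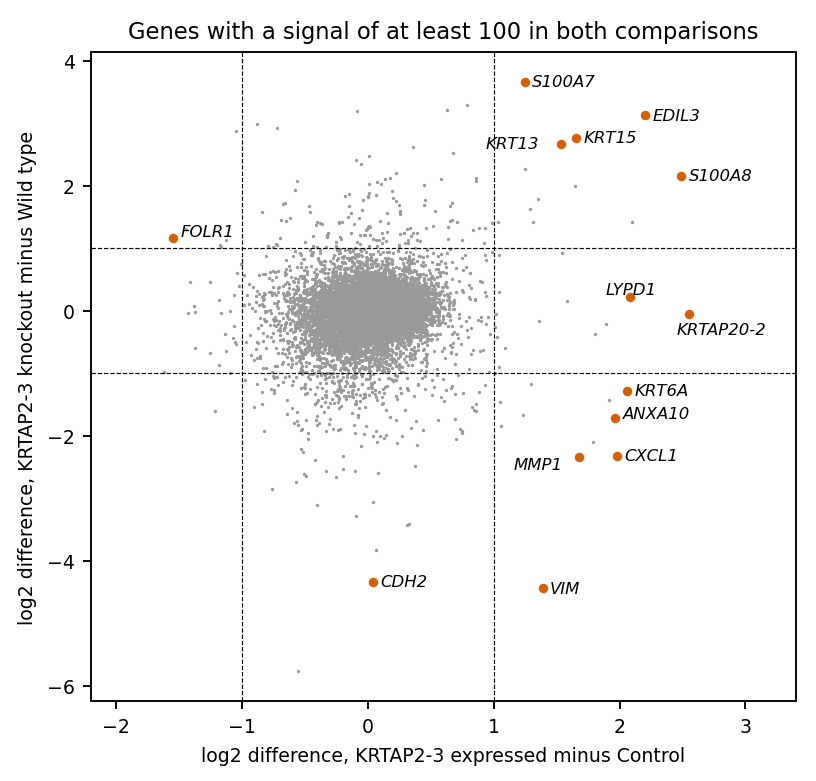
Log2 difference of expressed minus Control (horizontal axis) and of knockout minus Wild type (vertical axis) for each gene with a signal of at least 100, with dashed lines at 2-fold and selected genes in colour. VIM, CXCL1 and MMP1 lie at the lower right, higher on the expressed array and lower on the knockout array.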

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

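The alternatives that require a signal of at least 100 were chosen only after the results were seen, and the others before the data were examined. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. The authors' table gives no Wild type minus Control value, so that alternative was not run there. KRTAP2-3 kept its direction at both probes under every alternative that gave a value, with knockout minus Wild type at −2.34 under normexp and between −2.56 and −2.53 otherwise. The counts of genes were lowest under normexp and next lowest with a signal of at least 100. Most genes called in each comparison had signals under 100 on both arrays, and that range limits what these arrays resolve.

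For expressed against Control (4418 genes), the count was 44 under normexp (25 higher, 19 lower), 2298 under quantile normalization, 1572 with detection on all 4 arrays, 1574 in the authors' table, 8676 at 1.5-fold, 1581 at 3-fold and 98 with a signal of at least 100. Against the Wild type array it was 1733 (768 higher, 965 lower), or 215 with a signal of at least 100 (130 higher, 85 lower). For knockout against Wild type (2477 genes), it was 313 under normexp (114 higher, 199 lower), 934 both with detection on all 4 arrays and in the authors' table (431 higher, 503 lower), 1350 without a filter on dim probes, 6255 at 1.5-fold, 841 at 3-fold and 487 with a signal of at least 100. Quantile normalization gave 2251 (1123 higher, 1128 lower), and the Control array as comparator 2909 (469 higher, 2440 lower), or 482 with a signal of at least 100 (122 higher, 360 lower). For Wild type against Control (3817 genes), it was 131 under normexp (57 higher, 74 lower) and 2236 under quantile normalization (873 higher, 1363 lower). Detection on all 4 arrays gave 1333, no filter 2485, 1.5-fold 8622, 3-fold 1149 and a signal of at least 100 gave 241. Genes opposite in both comparisons (439) numbered 9 under normexp, 194 under quantile normalization, 74 both with detection on all 4 arrays and in the authors' table, 157 without a filter, 1822 at 1.5-fold, 70 at 3-fold and 18 with a signal of at least 100. The fold, signal and detection limits admit fewer or more genes by construction. Normexp replaced the background subtraction and added an offset together, and for it, quantile normalization and the other comparator the cause was not tested.

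The lists that stood apart numbered 13 to 19 for expressed against Control, 12 to 18 for knockout against Wild type and 14 to 18 for Wild type against Control over the alternatives. These totals did not always hold the same lists. With the other comparator 15 lists were apart for the expressed array and 18 for the knockout array. Of the 14 and 15 lists apart in the main setting, only 5 and 8 were then apart with the same sign. Beside unmatched random lists 9 of the 14 were, and as means 9 of the 15. In the knockout comparison the mesenchymal, protease, NF-κB, AP-1, actin and metallothionein lists were apart with the same sign under all 12 settings, and for the expressed array the G2/M and interferon lists. Among lists not apart, 16 of 23 and 13 of 22 medians changed sign under some setting. Among lists apart fewer did. For expressed against Control these were endothelial markers under quantile normalization (0.15) and, against the Wild type array, endothelial markers (0.26), G1/S (−0.10), unfolded protein response (−0.25), heat shock (−0.022), ribosome biogenesis (−0.30) and histone genes (−0.21). For knockout against Wild type they were, as means, keratins (0.0035) and S100 and annexin genes (−0.053), and against the Control array keratinocyte differentiation (−0.043), antigen presentation (−0.041), glycolysis (0.073), unfolded protein response (0.22), ribosome biogenesis (0.44) and S100 and annexin genes (−0.091). A mean weights a few large members more by construction, and for the rest the cause was not tested. Of the named genes called at least 2-fold different, 0 changed sign under the alternatives run on single genes. Those did not include the other comparator. Sign changes of smaller differences were not counted. For the expressed array 668 values of all named genes stayed within their error and 147 moved further, and for the knockout array 848 and 109.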

Other observations

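The tests below were chosen only after the results were seen, except that the test of whether the level of KRTAP2-3 acts in both directions was written before its own value was known, with a signal limit of 100 that had been chosen after the data were seen.

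Single genes also set pairs of arrays apart. Among 14755 genes with a signal of at least 100 on any array, 23 had both the Control and expressed arrays at least 2-fold away from both the Wild type and knockout arrays, 19 of them higher on Control and expressed. Chosen after their values were seen, these include the complement gene C3 (signals of 1499, 1695, 348 and 362 on Control, expressed, Wild type and knockout), the calcium-binding protein gene S100P (287, 293, 31.9 and 38.0), and IFITM1, an interferon-induced membrane protein gene (3065, 1867, 818 and 722). The pairing of Control with knockout set 8 genes apart, and that of Control with Wild type 11. The SD of the log2 difference over these genes was lowest for expressed and Control (0.280) and highest for knockout and Control (0.434), with 0.355 for Wild type and Control and 0.418 for knockout and Wild type.

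Small nucleolar RNAs of the H/ACA class, which guide pseudouridylation of ribosomal RNA, were highest on the Wild type array for 70 of 93 genes. Their median was 0.84 for Wild type minus Control, with 40 at least 2-fold higher, −0.37 for knockout minus Wild type and 0.10 for expressed minus Control. SNORA1 had signals of 371, 519, 1146 and 820 in the same order of arrays and was chosen after its values were seen. The related small Cajal body RNAs, 18 genes, had a median of 0.58 for Wild type minus Control.

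Far more genes were lower than higher against the Control array, on the expressed (94.8% of those that differed), Wild type (92.2%) and knockout arrays. The excess depended on the processing. On the expressed array normexp gave 25 higher and 19 lower, and quantile normalization 841 and 1457. On the Wild type array they gave 57 and 74, and 873 and 1363. An effect of KRTAP2-3 expression as the whole source of this excess is argued against, since 83.9% were lower on the knockout array too, where neither probe of KRTAP2-3 was higher than on Control. For genes with a signal of at least 100 such an effect stays open: 5.36% of the 56 lower genes were also at least 2-fold lower than on the Wild type array (27.8% in simulated arrays without an effect), but that array was itself higher than Control at the gene's own probe. A difference between arrays in the low signal range is a candidate explanation, since dim spike-in RNAs differed by −0.678 more than bright ones. It rests on 3 dim spike-ins.

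The mesenchymal, protease and cytokine lists had medians below 0 on the knockout array, with 6 of 25, 11 of 23 and 11 of 31 members at least 2-fold lower and 1, 0 and 5 higher. For these 3 lists a Wild type array out of place is argued against, since against Control their medians lay between −0.80 and −0.48, below all matched random lists. That does not extend to the AP-1 list, with −0.65 against Wild type but −0.11 against Control. Its Wild type minus Control median was 0.37. The low signal range is argued against as well for the 3 lists, since with signals of at least 100 the highest of their percentiles was 0.08. Whether the level of KRTAP2-3 sets these genes in both directions stays open. The 303 genes lower on the knockout array had a median of −0.12 on the expressed array (quartiles −0.36 and 0.15), with 114 above 0. The label of that array was borne out at the shared probe but not at the gene's own. An effect of the knockout and a difference between clones or cultures both remain open and untested, since there was 1 array of each.

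The small nucleolar RNAs stood out on the Wild type array. A different scale of that array is argued against, since no bright spike-in was more than 0.106 higher than on Control, below the lower quartile of these genes (0.29). A lowering by the knockout could not be the whole source, since it cannot raise the Wild type array above Control (median 0.84). The knockout array was 0.47 above Control in the median (quartiles 0.21 and 0.68). That value cannot tell whether the knockout lowered these RNAs from the Wild type level, since Control is not its comparator. Better recovery of short RNA may contribute and stays open, because the C/D class of small nucleolar RNAs, 134 genes, had a median of 0.25 (quartiles 0.01 and 0.50). Whether the probes report the mature short RNAs or longer transcripts that contain them was not tested. A difference between the cultures in the making of ribosomes was not tested.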
